A study of Mus musculus with 30 samples.

How the data were processed

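The series holds 30 samples of mouse (C57BL/6) testicular germ cells at 4 stages: primitive type A spermatogonia (PriSG-A, day 6 after birth), type A spermatogonia (SG-A, day 8), pachytene spermatocytes (pacSC, adult) and round spermatids (rST, adult). Of these, 10 are ATAC-seq libraries, 3 for each spermatogonial stage and 2 for each of the later stages. ATAC-seq cuts open chromatin with the transposase Tn5 and sequences the fragments, so that a pile-up of reads marks accessible DNA. The other 8 Hi-C samples and 12 ChIP-seq and input samples are not analysed here.

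The data used were 4 deposited ATAC-seq peak lists, 1 per stage. The labels of all replicates of a stage name the same list. The PriSG-A list was assigned from those labels and by exclusion of the other 3, because its deposited name is garbled. With 1 list for all replicates of a stage, replicates are not separable in these files. How the replicates were combined, the peak caller and its settings are not given in the sources used here. Bowtie2 2.2.5, Bowtie and SAMtools are named in the submitters' processing notes, without a role. Whether reads were shifted for the Tn5 offset is not given in the sources used here. The read depth behind each list is unknown.

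Each deposited peak carries a score, a signal value, a −log10 q-value and a summit offset in bp. Tested on the values, the deposited score equals 1000 times the signal value divided by the peak width, with a cap at 1000, for 100% of peaks in each list within a tolerance of 1. The deposited signal value is therefore an area over the peak that grows with its width, and it is not a fold enrichment. The lowest signal value was 20.0 in each list, and the smallest gap between neighbouring peaks was 101 bp, so the authors' lists had passed a minimum area and a joining of near neighbours. These are the authors' values for each peak, and they were used only to rank, filter or describe peaks. A −log10 q of at least 5 was applied to every list alike. The q-values may depend on read depth, which is unknown, so shares of peaks reaching that threshold compare lists only.

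The genome build was checked because the submitters' processing notes name mm10. Peaks ran past the last gene of a RefSeq gene table on GRCm38 (the assembly that mm10 denotes) on 10 of 21 chromosomes, by up to 7.2 Mb, on chromosome 7. Summits of SG-A peaks with a −log10 q of at least 2.5 lay within 1000 bp of a GRCm38 protein-coding gene end in a median of 5.31% of cases per chromosome, against 4.42% after shifting the summits by 10 multiples of 37 kb. On 20 of 21 chromosomes the share was below 2 times the shifted share. The positions are therefore not on mm10. The extents of the chromosomes fit the older mm9 assembly, which no source used here names. Positions are given as the files give them, 1-based. A genome sequence or gene annotation on that assembly was not used here, and coordinates were not converted. The planned promoter, gene list, genomic location and sequence motif results were left out for this reason, and no gene is named.

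Peaks on chromosomes 1 to 19, X and Y were merged where they overlapped. No peak overlapped another of its list, and none lay off these chromosomes, so each listed peak is 1 region. Regions of 2 lists were called shared at an overlap of at least 1 bp, counted in Python rather than with the planned bedtools. The overlap expected by placement was taken from 100 random placements of one list within the listed span of each chromosome (random seed 1), and from 100 placements that moved each region by up to 500 kb. Union regions joined overlapping regions of the 4 lists. Densities are regions per Mb of the span between the first and the last listed peak of a chromosome over the 4 lists. The mouse autosomes and X carry the centromere at the low-coordinate end, so the high-coordinate end is called distal, and the distal zone is its last 10 Mb.

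With 1 list per stage, replicate error is not measurable here and no p-value between stages was computed. Ratios of values between stages compare lists only. Shares have 95% Wilson binomial intervals, and density ratios have 95% Poisson intervals on the log scale. Both cover counting error only. They leave out differences between animals and libraries, and they treat neighbouring regions as independent. Presence or absence in a list depends on the unknown depth of each stage, so "newly listed" and "not listed again" describe lists, not a measured gain or loss of accessibility.

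Before the data were examined, the overlap rules, the X comparison and the rule for named regions were fixed. The rule takes, per transition between consecutive stages, the 5 newly listed and the 5 not listed again regions of highest signal value. The position along chromosomes, the relation to chromosome length, the dense windows, the placement within 500 kb and the X density of newly listed regions were chosen after seeing the data. Alternatives were a −log10 q of at least 5, a reciprocal overlap of 50%, lists of equal length (the 6459 peaks of highest −log10 q), and, added later, leaving out the distal 10 Mb, distal zones of 5 and 20 Mb, counting each 100 kb window once, and leaving out 1 Mb windows with over 5 times the median number of regions. Relations with chromosome length are Pearson and Spearman correlations over 19 autosomes with two-sided permutation tests (100000 permutations, Benjamini-Hochberg adjustment over 12 relations).

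The counting code was tested on simulated lists of 30000 regions with the widths of pacSC peaks, the widest of them cut short. A list made with 40% shared regions gave 39.7%, an X density ratio of 0.5 gave 0.50, and a distal fold of 3 gave 2.96. Unchanged lists gave 0.97 for X and 0.98 for the distal zone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.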

Results

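Chromatin accessibility was compared across 4 stages of mouse spermatogenesis, from mitotic spermatogonia through meiosis to haploid spermatids. The ATAC-seq data comprised 3 libraries of PriSG-A, 3 of SG-A, 2 of pacSC and 2 of rST, each stage summarised by the authors as 1 peak list. The lists held 56792 open regions in PriSG-A, 88369 in SG-A, 33775 in pacSC and 6459 in rST. They covered 22.5, 38.4, 12.1 and 1.961 Mb of the genome. Median region width was similar, at 210 bp, 182 bp, 190 bp and 188 bp. The 95th percentile of width was 1297 bp in PriSG-A, 1636 bp in SG-A, 1136 bp in pacSC and 812 bp in rST. Regions over 5000 bp numbered 25 in PriSG-A, 44 in SG-A, 18 in pacSC and 13 in rST. Regions with a −log10 q of at least 5 made up 9.49% of the PriSG-A list, 18.5% of the SG-A list, 10.7% of the pacSC list and 3.30% of the rST list. Read depth is unknown and there is no replicate value, so error beyond counting cannot be measured for these counts. The longer lists came from 3 libraries each and the shorter from 2, so the number of libraries also differs with stage.

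The regions of highest signal value were common to all 4 stages. The region of highest signal value in the spermatogonial lists lay on chromosome 9, at 3005598 to 3038390 in PriSG-A (signal value 467590). A region on chromosome 1, at 24618314 to 24623073 in pacSC, ranked first in pacSC (196830) and in rST (141490), and held rank 3 in both spermatogonial lists. A region on chromosome 11, at 3026823 to 3048798 in pacSC, had counterparts among the first 5 of each other list. Each of the 5 regions of highest signal value in every list overlapped regions of the other 3. The region on chromosome 9 spanned 32793 bp in PriSG-A, against a median region width of 210 bp. No filter for repeated or multi-copy sequence was applied here, so mapping artefacts among these regions cannot be told apart from open chromatin.

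The 4 lists joined into 117075 union regions. SG-A alone held 52099 of them, or 44.5% (95% interval 44.2 to 44.8). PriSG-A alone held 15237 (13.0%, 12.8 to 13.2), pacSC alone 13709 (11.7%, 11.5 to 11.9) and rST alone 363 (0.310%, 0.280 to 0.344). The 2 spermatogonial stages shared 19500 regions with no later stage (16.7%, 16.4 to 16.9). All 4 stages shared 3306 (2.82%, 2.73 to 2.92).

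**Figure D1:**
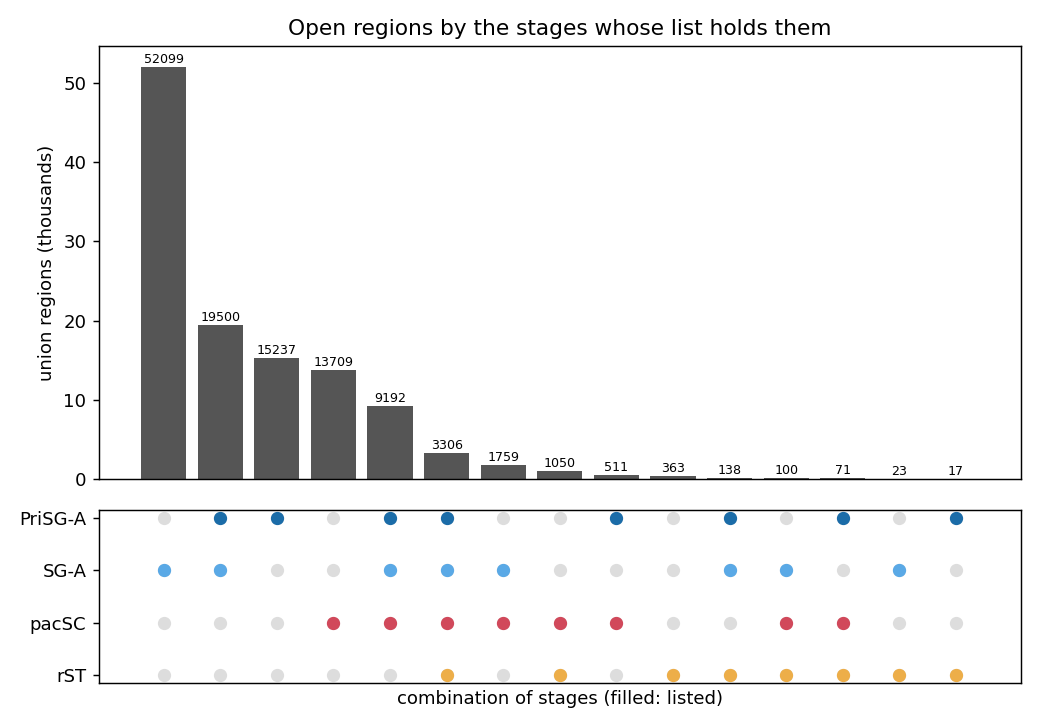
Number of union regions (bars, with counts printed above) for each combination of the 4 stages whose peak list holds them (filled dots). The SG-A-only class is the largest at 52099, and 363 regions are found in rST alone.

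The first transition, from PriSG-A to SG-A, asked how accessibility changes between day 6 and day 8 spermatogonia. Most PriSG-A regions were listed again: 40821 of 56792, or 71.9% (95% interval 71.5 to 72.2). Random placement within chromosomes gave 2.63% ± 0.0612 (SD over 100 placements), and placement within 500 kb gave 4.46% ± 0.0738. In the other direction, 54344 of 88369 SG-A regions, or 61.5% (61.2 to 61.8), had no PriSG-A counterpart. The newly listed regions were narrow, with a median width of 105 bp against 647 bp for SG-A regions already listed in PriSG-A. Only 0.953% of them reached a −log10 q of 5, against 46.4% of those already listed. With lists of equal length, 23.4% of SG-A regions were newly listed, and with a reciprocal overlap of 50% only 32.2% of PriSG-A regions were listed again.

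The newly listed SG-A regions of highest signal value lay on chromosome 7 at 19888681 to 19891032 (signal value 4970, 2352 bp wide), chromosome 11 at 69418019 to 69419939 (3642), chromosome 5 at 125620593 to 125622446 (3509), chromosome 11 at 97489777 to 97491279 (3363) and chromosome 2 at 119150424 to 119153141 (3222). All 5 were listed in SG-A alone. The nearest PriSG-A region was 2010 bp from the first and 35650 bp from the third. The PriSG-A regions not listed again, ranked within the PriSG-A list, were led by chromosome 10 at 7117425 to 7118122 (1075), chromosome 3 at 42018473 to 42019459 (953), chromosome 9 at 35494234 to 35495302 (857), chromosome 3 at 91121349 to 91122628 (833) and chromosome 17 at 18547207 to 18548216 (807). None of these 5 was listed at any other stage. The fourth ended 355 bp from an SG-A region.

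The second transition, from SG-A to pacSC, compared spermatogonia with cells in meiotic prophase. Few SG-A regions were listed again in pacSC: 14891 of 88369, or 16.9% (95% interval 16.6 to 17.1), against 0.965% ± 0.0325 by random placement and 1.45% ± 0.0391 by placement within 500 kb. Those listed again were the wide ones, with a median width of 1176 bp against 138 bp for those not listed again. Of the pacSC regions, 15478 of 33775, or 45.8% (45.3 to 46.4), were absent from the SG-A list. The spermatogonial regions found in pacSC were mainly those present at both earlier stages. Of union regions in both PriSG-A and SG-A, 38.9% (38.4 to 39.4) were also in pacSC. Of regions listed in SG-A but not PriSG-A, 3.44% (3.29 to 3.60) were in pacSC, and of those listed in PriSG-A but not SG-A, 3.68% (3.39 to 3.98). These groups also differed in strength. A −log10 q of 5 was reached by 46.4% of SG-A regions already in PriSG-A and by 0.953% of those newly listed. Presence at both stages therefore cannot be told apart from strength here. At equal list length 56.5% of SG-A regions were listed again, and with a reciprocal overlap of 50% the share was 6.65%. The share of pacSC regions absent from SG-A was 15.4% with a −log10 q of at least 5 in both lists and 82.6% with the reciprocal overlap.

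The newly listed pacSC regions of highest signal value lay on chromosome 8 at 130244921 to 130247365 (signal value 6360), chromosome 5 at 150625688 to 150628854 (6009), chromosome 3 at 48189002 to 48191062 (5707), chromosome 14 at 66242915 to 66245332 (5333) and chromosome 19 at 58946904 to 58951703 (5308). Those on chromosomes 8, 5 and 19 lay 1.34, 1.91 and 2.39 Mb from the distal end. Those on chromosomes 3 and 14 were also listed in rST, and the other 3 were listed in pacSC alone. The region on chromosome 8 lay 859 bp from an SG-A region. The SG-A regions not listed again, ranked within the SG-A list, were led by chromosome 1 at 173007525 to 173012996 (18716), chromosome 6 at 127099355 to 127105799 (16164), chromosome 13 at 21923060 to 21926622 (15220), chromosome 14 at 51707825 to 51711628 (14862) and chromosome 13 at 21901058 to 21904643 (14128). All 5 were in PriSG-A too, and the one on chromosome 1 was in rST.

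The third transition, from pacSC to rST, compared meiotic with haploid cells. The rST list was almost contained in the pacSC list: 5704 of 6459 rST regions, or 88.3% (95% interval 87.5 to 89.1), overlapped a pacSC region, against 0.855% ± 0.127 by random placement and 1.72% ± 0.152 by placement within 500 kb. Also, 73.4% (72.3 to 74.4) overlapped PriSG-A and 74.4% (73.3 to 75.4) SG-A. Of the pacSC regions, 4821 of 33775, or 14.3% (13.9 to 14.7), were listed again in rST. A spermatogonial list held 76.8% (75.6 to 78.0) of union regions shared by pacSC and rST, against 45.5% (44.9 to 46.2) of those in pacSC and not in rST. These groups also differed in strength and width. A −log10 q of 5 was reached by 40.9% of pacSC regions listed again in rST and by 5.69% of the others. Their median widths were 690 bp and 153 bp. Presence in a spermatogonial list therefore cannot be told apart from strength here. With a reciprocal overlap of 50% required, 71.5% of rST regions had no pacSC counterpart and 5.45% of pacSC regions were listed again. At equal list length the shares were 42.7% and 44.2%, and with a −log10 q of at least 5 in both lists 4.73% of pacSC regions were listed again.

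Of the 755 rST regions not listed in pacSC, the 5 of highest signal value were all listed in PriSG-A and SG-A. They lay on chromosome 1 at 85252777 to 85254879 (signal value 2011), 87517369 to 87519072 (988) and 85277738 to 85278962 (909), on chromosome 6 at 47624883 to 47626286 (1214) and on chromosome 7 at 67011999 to 67013039 (1131). Each lay within 4017 bp of a pacSC region. Those on chromosomes 1 and 6 lay in 1 Mb windows dense in rST regions. These windows held 123 and 49 rST regions on chromosome 1 and 62 on chromosome 6, against a median of 3 per occupied window. Without dense windows the newly listed rST share was 8.73%, against 11.7% in the full list. The pacSC regions of highest signal value not listed again were at chromosome ends. Of these, 3 lay on X at 166609462 to 166628654 (32932), 166577679 to 166589532 (24452) and 166504257 to 166509595 (12685), within 0.141 Mb of the distal end, where the mouse X carries the pseudoautosomal region shared with Y. The other two lay on chromosome 11 at 120684781 to 120688204 (10021) and on chromosome 7 at 150480735 to 150483263 (8999), 1.16 and 2.04 Mb from the distal end. All 5 were listed in both spermatogonial stages.

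In each transition the regions of highest −log10 q were listed again most often. Of the highest 10% of the PriSG-A list, 99.98% of regions (95% interval 99.90 to 99.997) were found in SG-A, and of the lowest 10%, 43.3% (42.1 to 44.6). For SG-A regions found in pacSC these shares were 85.4% (84.6 to 86.1) and 3.80% (3.42 to 4.22). For pacSC regions found in rST they were 55.3% (53.6 to 57.0) and 3.02% (2.49 to 3.65).

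**Figure D2:**
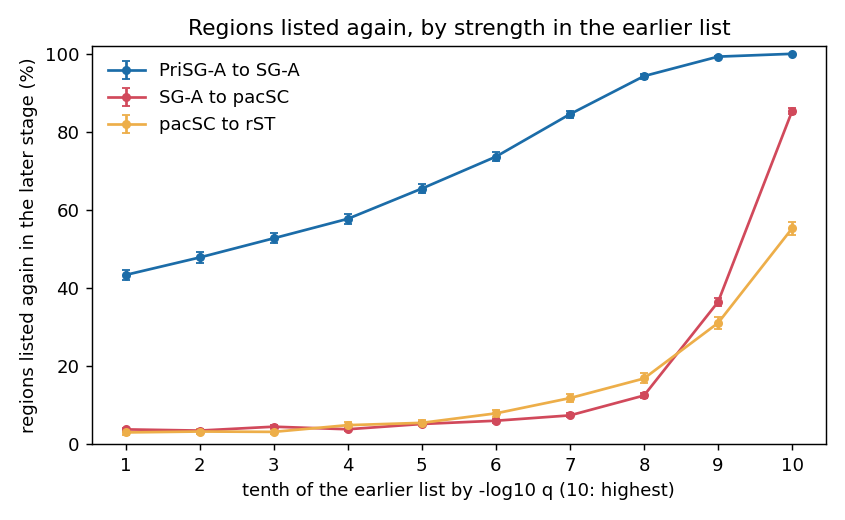
Percent of regions listed again in the next stage (y axis) by 10 equal classes of the earlier list ranked on −log10 q (x axis, 10 is highest), for 3 transitions. Bars are 95% Wilson intervals, and the highest classes reach 99.98%, 85.4% and 55.3%.

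The sex chromosomes were compared with autosomes because X and Y are transcriptionally silenced in pachytene spermatocytes. X carried fewer regions per Mb than autosomes at every stage. The ratio was 0.617 in PriSG-A (95% interval 0.591 to 0.643), 0.427 in SG-A (0.410 to 0.444), 0.350 in pacSC (0.326 to 0.376) and 0.407 in rST (0.350 to 0.474). Male cells carry 1 copy of X before meiosis. In rST the ratio was 2.18 when the 213 peaks with a −log10 q of at least 5 were used, and 0.146 when each 100 kb window was counted once. The X regions were clustered. The 1 Mb window from 120000001 to 121000000 held 245 regions in PriSG-A, 260 in SG-A, 143 in pacSC and 59 in rST, out of 2273, 2481, 781 and 172 X regions. The window from 121000001 to 122000000 held a further 221, 252, 120 and 49, and that from 122000001 to 123000000 held 179, 179, 56 and 14.

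New regions on X were rarer still in the full lists. Of the SG-A regions newly listed against PriSG-A, 973 lay on X, at 0.269 (0.253 to 0.287) of the autosomal density. Of the pacSC regions newly listed against SG-A, 131 lay on X, at 0.126 (0.106 to 0.150) of the autosomal density. At equal list length the values were 0.128 in SG-A and 0.171 in pacSC, so the lower value in pacSC was not found with lists of equal length. With a −log10 q of at least 5 in both lists the values were 0.589 (0.535 to 0.650) in SG-A and 0.134 (0.0556 to 0.324, on 5 X regions) in pacSC, and with each 100 kb window counted once the values were 0.436 and 0.191. Newly listed regions made up 16.8% (14.3 to 19.6) of pacSC regions on X and 46.6% (46.1 to 47.2) of those on autosomes. The share of SG-A regions listed again in pacSC was not lower on X, at 21.5% (19.9 to 23.1) against 16.7% (16.4 to 16.9) on autosomes. For PriSG-A regions found in pacSC it was lower on X, at 22.97% (21.3 to 24.7) against 25.7% (25.3 to 26.0). These shares are not matched for strength. The median −log10 q was higher on X than on autosomes in SG-A (3.08 against 2.71) and in PriSG-A (2.63 against 2.42), and regions of higher −log10 q were listed again more often. In rST, 3 of 172 X regions were newly listed, or 1.74% (0.595 to 5.00), against 12.1% (11.3 to 12.9) on autosomes. On Y the listed span was 2.77 Mb. It held 106 regions in PriSG-A, 115 in SG-A, 92 in pacSC and 54 in rST, and 46.96% (38.1 to 56.0) of the SG-A regions there were listed again in pacSC.

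**Figure D3:**
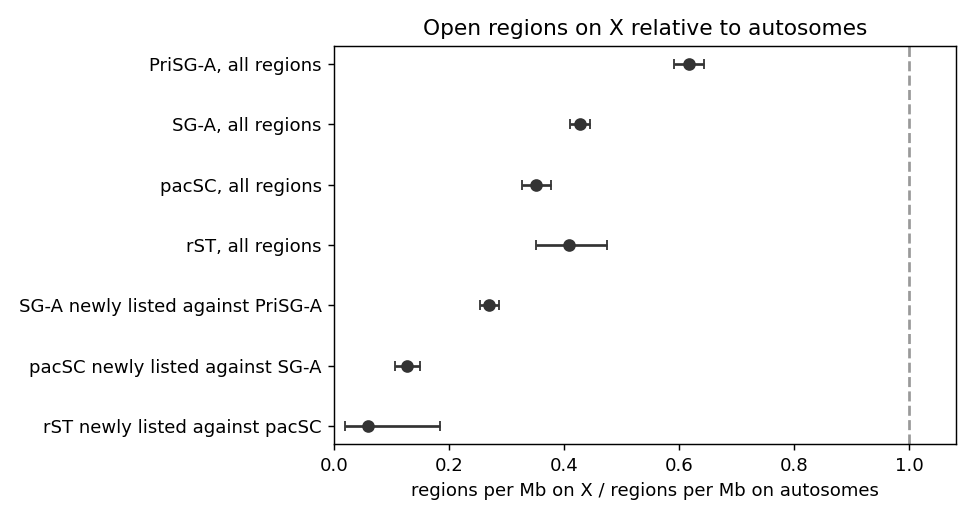
Density of open regions on X divided by that on autosomes (x axis, regions per Mb over regions per Mb), for all regions of each stage and for regions newly listed against the preceding stage. Points are ratios with 95% Poisson intervals, and the dashed line marks equal density. All points lie below 1, from 0.617 in PriSG-A to 0.0589 for new rST regions.

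Open regions of pacSC were concentrated at the distal ends of autosomes, a position chosen for study after seeing the data. In pacSC 25.4% of autosomal regions (95% interval 25.0 to 25.9) lay in the distal 10 Mb, against 8.92% (8.69 to 9.17) in PriSG-A, 10.7% (10.5 to 10.9) in SG-A and 8.58% (7.91 to 9.30) in rST. The density there was 3.99 times that elsewhere on autosomes in pacSC (3.89 to 4.09), 1.15 times in PriSG-A (1.11 to 1.18), 1.41 times in SG-A (1.38 to 1.44) and 1.099 times in rST (1.01 to 1.201). With a zone of 20 Mb the rST value was 0.926, and with each 100 kb window counted once the pacSC value was 1.73. The pacSC density was 75.4 regions per Mb in the last 1 Mb and 81.4 in the next, fell to 25.4 between 5 and 10 Mb and to 11.8 between 20 and 40 Mb. In the last 1 Mb SG-A, with the longest list, had 42.4 regions per Mb. At the centromeric end the fold was 1.24 in pacSC (1.196 to 1.29), against 1.35 in PriSG-A (1.31 to 1.39), 1.03 in SG-A (1.001 to 1.05) and 0.586 in rST (0.521 to 0.658).

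The distal concentration was stronger in the newly listed regions of pacSC than in those already listed in SG-A. Their distal fold was 6.74 (6.52 to 6.97) against 2.18 (2.10 to 2.27). Over all pacSC regions, the distal concentration was seen on each autosome, with a fold from 2.203 to 6.68 and a value above that in SG-A on 19 of 19. The newly and already listed regions were not compared by chromosome. The densest pacSC window was on chromosome 7 at 151000001 to 152000000, with 162 regions against 17 in PriSG-A, 39 in SG-A and 2 in rST. On chromosome 11 at 121000001 to 122000000 pacSC had 116 regions against 25, 29 and 4. On chromosome 2 at 180000001 to 181000000 it had 113 against 45, 78 and 4. On X the distal fold was 0.833 in PriSG-A (0.692 to 1.004), 0.946 in SG-A (0.7996 to 1.12), 1.35 in pacSC (1.04 to 1.74) and highest in rST, at 2.99 (1.99 to 4.48, on 28 distal X regions).

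**Figure D4:**
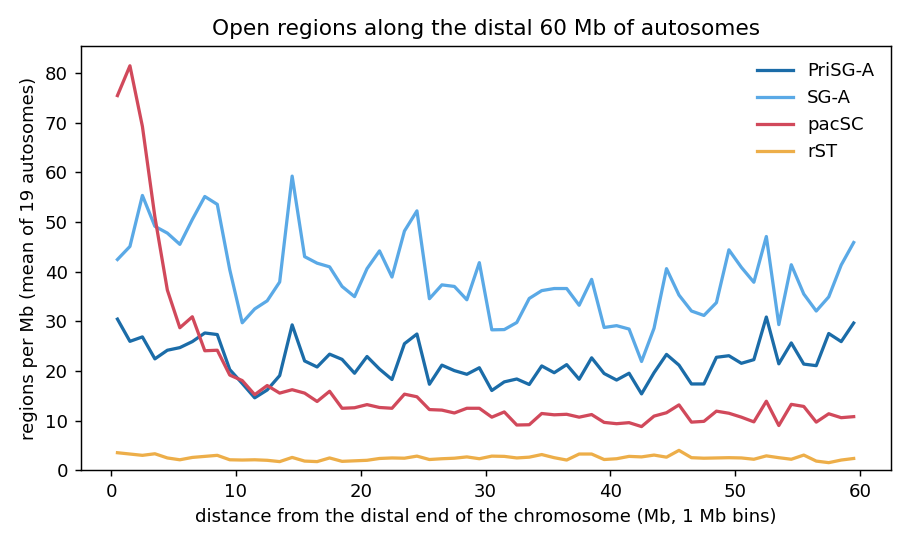
Open regions per Mb (y axis, mean of 19 autosomes) in 1 Mb bins of distance from the distal end (x axis) for each stage. The pacSC line starts at 75.4 and 81.4 regions per Mb and drops below the SG-A line within the first 10 Mb.

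**Figure D5:**
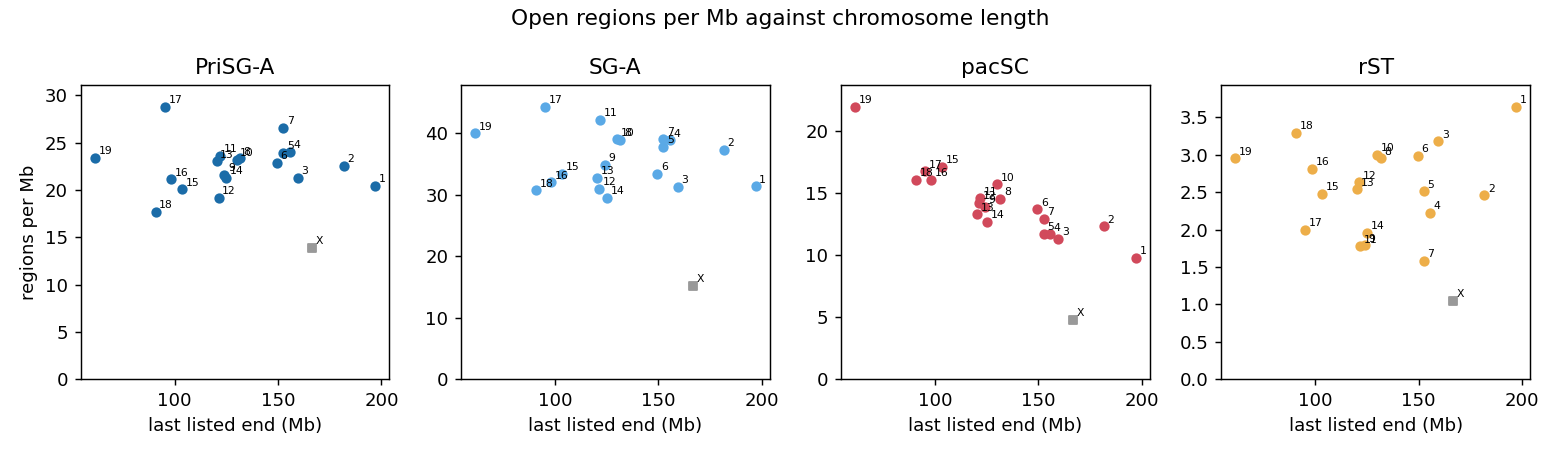
Open regions per Mb (y axis) against the last listed position of each chromosome (x axis, Mb), 1 panel per stage, with autosomes as circles and X as a square. In pacSC the values run from 21.96 on chromosome 19 to 9.79 on chromosome 1, and X lies at 4.78.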

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

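The alternatives that leave out the distal 10 Mb or dense 1 Mb windows, count each 100 kb window once, or concern the distal zone or the X ratio of newly listed regions were chosen after the data were seen. Of 80 alternative values, 21 stayed within the main interval (counts within 1.5 times), 57 moved and 2 reversed. Of the 21, 10 could not move because the setting left the list as it was (no overlapping peaks, none off the main chromosomes, and rST as the shortest list), which leaves 11 of 70. The cause was not tested, beyond fewer regions entering the shorter lists. No paired analysis was possible because each stage has 1 list for all its replicates, and for the same reason no replicate was left out in turn. Comparisons chosen beforehand on promoter windows, promoter and distal regions, genomic location, genes with a promoter region, gene lists and sequence motifs were not run, since no annotation or sequence of the files' assembly was used. Unknown depth limits every comparison of list lengths.

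With a −log10 q of at least 5 the lists held 5392 (PriSG-A), 16309 (SG-A), 3619 (pacSC) and 213 (rST) regions. With that threshold in both lists, the shares listed again were 99.2% of PriSG-A in SG-A, 18.5% of SG-A in pacSC and 4.73% of pacSC in rST, and the newly listed shares were 67.4% of SG-A, 15.4% of pacSC and 10.3% of rST. X to autosome ratios were 0.710, 0.627 and 0.246 in PriSG-A, SG-A and pacSC, reversed to 2.18 (1.44 to 3.29) in rST, and were 0.589 for new SG-A and 0.134 for new pacSC regions. Distal folds were 1.06, 1.31, 4.68 and 1.59 in stage order.

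With a reciprocal overlap of 50% the shares listed again were 32.2%, 6.65% and 5.45% over the transitions in order, and the newly listed shares 79.3%, 82.6% and 71.5%. At equal list length the shares listed again were 77.5%, 56.5% and 44.2%, and the newly listed shares 23.4%, 41.9% and 42.7%. X ratios at equal length were 0.741, 0.373 and 0.269 in PriSG-A, SG-A and pacSC, 0.128 for new SG-A and 0.171 for new pacSC regions, and distal folds were 1.09, 1.26 and 3.61. Without dense 1 Mb windows the newly listed shares were 62.1%, 42.3% and 8.73%, and 15.5% of pacSC regions were listed again in rST.

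Without the distal 10 Mb the X ratio was 0.424 in pacSC and 0.161 for new pacSC regions. With each 100 kb window counted once it was 0.559 in SG-A, 0.146 in rST, 0.436 for new SG-A and 0.191 for new pacSC regions, and the distal folds were 1.07, 1.15 and 1.73 in PriSG-A, SG-A and pacSC. With a distal zone of 5 Mb the folds were 1.37 in SG-A, 5.39 in pacSC and 1.22 in rST. With 20 Mb they were 1.02, 1.29 and 2.79 in PriSG-A, SG-A and pacSC, and reversed to 0.926 (0.863 to 0.993) in rST.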

Other observations

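The following tests were chosen only after the result was seen: the distal bias common to all libraries, the X yield common to all stages with its checks at equal list length and at a −log10 q of at least 5, the counts with each 100 kb window taken once, the return of distal pacSC regions in rST, the dense windows and the relation with chromosome length.

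Shorter autosomes carried more open regions per Mb in pachytene spermatocytes, and no such relation was detected at the other stages. Chromosome 19 had 21.96 regions per Mb in pacSC and chromosome 1 had 9.79. Over the 19 autosomes, which are not independent replicates, density and length gave Pearson's r = -0.90 and Spearman's rho = -0.88, each with a permutation p = 1e-05, the smallest the permutations can give (adjusted p = 4e-05 and 0.00012). Without chromosomes 1 and 19, the farthest from the median length, r was -0.84. Without the distal 20 Mb of each chromosome, r was -0.87 and rho -0.82, so the distal zone alone did not carry the relation. It was computed on the full lists only, not at equal list length or at a −log10 q of at least 5. Counting each 100 kb window once was not tried for it either. No technical explanation of the relation was tested. In PriSG-A r was 0.03 and rho 0.13 (permutation p = 0.912 and 0.604), in SG-A -0.13 and -0.06 (permutation p = 0.598 and 0.797), and in rST 0.10 and 0.06 (permutation p = 0.680 and 0.821), with adjusted p of at least 0.879 for each. The adjustment covers 12 relations per coefficient.

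A few windows held many regions at several stages. On chromosome 1 at 85000001 to 86000000 there were 179 regions in PriSG-A, 198 in SG-A, 25 in pacSC and 123 in rST, which was 41.0 times the rST median of 3 regions per occupied window. On chromosome 6 at 47000001 to 48000000 there were 62, 61, 51 and 62 regions. On chromosome 5 at 95000001 to 96000000 there were 133 in PriSG-A, 57 in SG-A and 0 in both later stages, and on chromosome 17 at 13000001 to 14000000 there were 192, 151, 12 and 2. On chromosome 10 at 80000001 to 81000000 SG-A had 256 regions against 117 in PriSG-A, 43 in pacSC and 2 in rST.

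The distal concentration of pacSC regions on autosomes was weighed against 4 technical explanations. Weak peaks near the threshold are argued against by a distal fold of 4.68 in pacSC (4.35 to 5.03) and 1.31 in SG-A (1.25 to 1.38) at a −log10 q of at least 5, and a bias common to all libraries by a pacSC fold 2.86 times that of SG-A (2.58 to 3.17) at equal list length. A few dense clusters are argued against as the whole cause, by counting each 100 kb window once. The pacSC fold then exceeded that of SG-A on 19 of 19 autosomes, and on 18 when SG-A was reduced to as many regions. It was then 1.73 in pacSC and 1.24 in the reduced SG-A list. Counting windows caps the fold where regions are dense (44.0 per Mb in the distal zone of pacSC). The lower pacSC value therefore does not measure how much clusters contribute. Higher detection of any open distal region in the pacSC libraries stays open. Distal SG-A regions were listed again in pacSC 1.77 times as often as others (27.2% against 15.4%). The ratio was 4.13 in the lowest 10% by −log10 q and 1.16 (97.5% against 84.3%, near the ceiling) in the highest 10%. The pacSC list was itself 3.99 times as dense in the distal zone as elsewhere, which raises such overlap under any cause. Overlap expected by placement was not computed for the zone alone, so these shares cannot decide the question. A base composition bias, which may raise distal detection, was not tested. A difference of the stage itself in distal accessibility also stays open as untested.

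The scarcity of new pacSC regions on X was weighed in the same way. The distal concentration of autosomal regions is argued against as its whole cause in the full lists. Without the distal 10 Mb of every chromosome the X to autosome ratio rose from 0.126 (0.106 to 0.150) to 0.161 (0.133 to 0.194). It stayed under the 0.276 (0.259 to 0.295) of new SG-A regions. A partial contribution stays open, and the zone was not left out at equal list length. A lower yield on X common to all stages cannot be told apart from a pacSC effect, because the lower pacSC value was not found at equal list length. The ratio for new pacSC regions was 0.468 times that for new SG-A regions in the full lists (0.390 to 0.562) and 0.228 times with a −log10 q of at least 5 in both lists (0.0939 to 0.552, on 5 and 421 X regions), but 1.34 times at equal list length (0.700 to 2.57, on 31 and 13 X regions). A difference of the stage itself was not tested and stays open too.

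Lower sensitivity as the reason for the short rST list cannot be told apart from a difference of the stage, since depth is unknown. The pacSC regions among the highest 10% by −log10 q were listed again in rST 13.96 times as often as those of the lower 50% (12.9 to 15.1), at 55.3% against 3.96%. The same comparison, added after the result was seen, gave 20.5 times (19.6 to 21.5) from SG-A to pacSC and 1.87 times (1.85 to 1.89) from PriSG-A to SG-A, so the preference for strong regions does not single out the rST list. Among the highest 10% of pacSC regions, 33.1% (30.2 to 36.2) of 963 distal regions were listed again in rST, against 63.5% (61.5 to 65.4) of 2337 other autosomal regions. The distal folds of the full lists, 3.99 in pacSC and 1.10 in rST, already differ in this way. The distal and other regions were not matched for strength within the highest 10%. These shares therefore do not decide between lower sensitivity and a difference of the stage.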
